A study of Homo sapiens with 20 samples.

How the data were processed

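The data are RNA sequencing libraries of THP1 cells treated for 24 h with recombinant human CYR61 at 0, 0.05, 0.5 or 5 µg/ml, with 5 libraries per dose and 20 in total. The groups and replicate numbers were taken from the labels. The submitters' processing notes name bcl2fastq, STAR, Subread featureCounts and Salmon without their roles. The genome build, the annotation release and the strand setting of the counting were not given in the sources used here, so no coordinates are reported and genes that overlap on opposite strands are uncertain. The deposited gene table holds a raw count per gene and library, with no normalisation, as its whole numbers show. The authors also deposited a table for each dose with log2 fold changes and their confidence limits per the file headers, computed with a test and software that are not named. The p-value columns of those deposited tables hold raw and adjusted p-values of the authors' comparisons. One of them also holds deposited log2 expression values per library. For 17964 genes, log2 CPM recomputed from the filtered counts with TMM factors matched these to within 5e-09. With library size alone the largest difference was 0.028.

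Of 60871 genes listed in the count table, 200 were repeats with identical counts and were removed, leaving 60671. Depth ranged from 28898244 to 43477179 counts per library. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 24669 genes. Between 2 libraries of a group the chi-square per gene was 2.88 to 9.43 over 40 pairs, where counting noise alone gives 1, and the median biological coefficient of variation was 4.45% over 5864 abundant genes. All computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

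The comparisons, tests, alternatives and gene lists were fixed before the data were examined. All 20 libraries entered 1 fit with a mean per group and 16 residual degrees of freedom. TMM factors, robust dispersion estimates and edgeR's quasi-likelihood F-test were used, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. Each dose was compared with control and with the next lower dose, and a slope was fitted over dose levels 0 to 3. Normalised CPM values use TMM-scaled library sizes.

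The genes named are, for each dose against control, the 10 largest rises and 10 largest falls among called protein-coding genes with an average logCPM of at least 1 whose 5 treated libraries all lay on one side of the 5 controls. For the slope, the 5 largest rises and falls under the same expression and biotype conditions are named. For each gene list and dose the rule adds the 3 members with the smallest p, and 12 genes were always included, among them CCN1, CCN2, ITGAM, ITGB2, TLR2, TLR4, TNF, IL1B, CXCL8, CCL2 and MMP9. The 30 gene lists were tested with camera on logCPM (prior count 2, preset correlation 0.01), adjusted over the 30 lists, and a list needed at least 5 tested members. They were tested again with an estimated correlation and with fry. Shares of counts were compared with exact permutation tests.

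The alternatives were RLE factors, library size alone, 2 other filters, DESeq2, limma voom with sample weights, the replicate number as a block, the 2 groups alone, glmTreat against a 1.2-fold change, a threshold of 0.01, protein-coding genes only, 1 surrogate variable, 2 other slopes, and leaving out each library in turn. Controls were also split into 2 and 3 libraries. The slope over the 15 libraries below 5 µg/ml and the counts of calls that DESeq2 and voom share with the authors' deposited tables were added after seeing the data. Each comparison was repeated on 100 splits of its libraries, the real one included.

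The tests were checked on simulated data in which 50 genes were changed at each of 4 folds in the 5 µg/ml group alone. The comparison with control recovered 18%, 40%, 94% and 96% of the genes changed 1.1-fold, 1.2-fold, 1.5-fold and 2-fold, with 10 false calls among 134 (7.46%), above the 5% aimed for. The direct comparison of 5 with 0.5 µg/ml recovered 8%, 42%, 94% and 96%, with 3 false calls among 123. In a separate simulation, with genes changed by equal steps up to the fold at 5 µg/ml, the slope recovered 10%, 60%, 96% and 100%, with 9 false calls among 142. In the first simulation no gene was called at 0.5 µg/ml, where none had been changed. A list of 20 members raised 1.2-fold was called by camera, and 0 of 29 unchanged lists were. Each simulated gene was drawn independently in each library, so these checks do not cover lists whose members vary together. Nor do they cover differences between libraries that many genes share, so the absence of calls at 0.5 µg/ml does not bear on those. In the real data the estimated correlation was 0.58 for mitochondrially encoded, 0.42 for immediate-early and 0.38 for histone genes. Other splits of the real libraries did give gene and list calls, up to 213 genes for 0.5 µg/ml against control, as reported in the last part.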

Results

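Gene expression was measured by RNA sequencing in THP1 cells, a human monocytic leukaemia line, after 24 h with recombinant human CYR61, a secreted matricellular protein also named CCN1. Total RNA had been depleted of ribosomal RNA before random-primed library preparation. There were 4 groups of 5 libraries each: untreated control, and CYR61 at 0.05, 0.5 and 5 µg/ml. The gene count table held between 28898244 and 43477179 counts per library, and 24669 genes passed the filter on low counts, of which 14613 were protein-coding and 4945 were lncRNA genes. The labels do not say whether the 5 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

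The comparison of 5 µg/ml with control asked which genes respond to the highest dose of CYR61. The largest rise among the genes chosen by the fixed rule was that of IGFBP3 (ENSG00000146674), which binds insulin-like growth factors, from 0.344 ± 0.107 to 7.87 ± 0.654 normalised CPM (mean ± SD, n = 5), a 22.7-fold change. IL4I1 (ENSG00000104951), a secreted amino acid oxidase, rose 17.5-fold from 1.62 ± 0.211 to 28.5 ± 2.02 CPM (SD, n = 5). MMP9 (ENSG00000100985), a gelatinase, rose 15.7-fold to 8.11 ± 0.784 CPM, and ICAM1 (ENSG00000090339), an adhesion ligand of leukocyte integrins, rose 10.2-fold to 12.1 ± 1.68 CPM (SD, n = 5). CTSG (ENSG00000100448), the granule protease cathepsin G, fell from 1656 ± 37.1 to 876 ± 14.6 CPM (SD, n = 5).

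In this comparison 1908 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1122 of them higher and 786 lower, as the plot of calls per comparison shows. Most changes were small, with 1566 of the 1908 under 1.5-fold. Of the 159 genes that changed at least 2-fold, 139 rose and 20 fell. The groups did not overlap in normalised CPM for 1379 of the 1908 genes. Over all genes tested the groups were separated in 7.48%, where chance gives 0.794%.

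**Figure D1:**
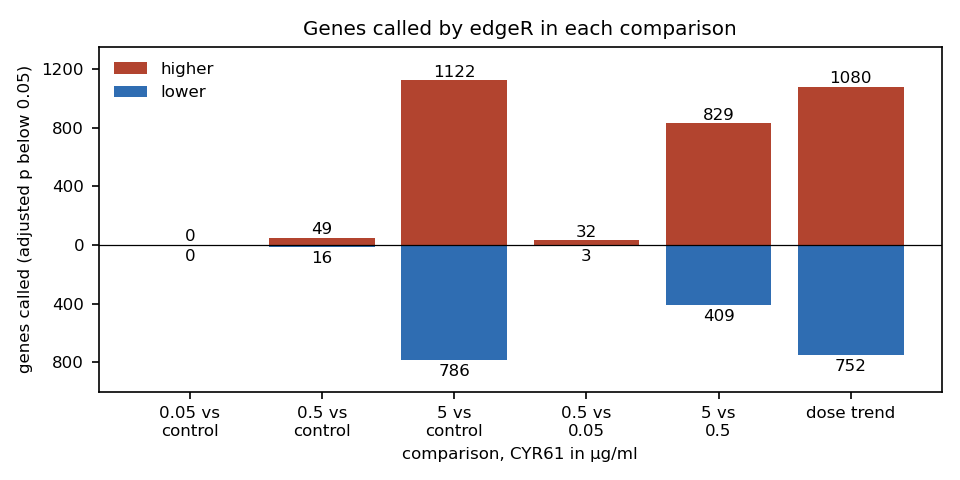
Number of genes called by edgeR (y axis, adjusted p below 0.05) in each comparison of CYR61 doses (x axis, n = 5 libraries per group), with genes higher above the zero line and genes lower below it. No gene was called at 0.05 µg/ml, 49 higher and 16 lower at 0.5 µg/ml, and 1122 higher and 786 lower at 5 µg/ml.

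Under the same rule, the other genes with the largest rises at 5 µg/ml included EBI3, a cytokine subunit, with a log2 fold change of 2.99 ± 0.14 (SE), and ADAMDEC1, a metalloprotease-related protein of macrophages, with 2.68 ± 0.16. BCL3, an atypical IkB protein, rose by 2.31 ± 0.11, the sulfotransferase gene CHST2 by 2.26 ± 0.11, the neutrophil chemokine gene CXCL8 by 2.16 ± 0.14, and CD83, a maturation marker of antigen-presenting cells, by 2.13 ± 0.17 (log2, SE, n = 5). The edgeR adjusted p of these 6 genes lay between 8.22e-26 and 3.55e-15. The largest fall under that rule was that of MSRB3, a methionine sulfoxide reductase gene, with a log2 fold change of -1.02 ± 0.10 (SE). It was followed by the glycosyltransferase gene UGT3A2 at -0.93 ± 0.079, CTSG at -0.92 ± 0.025, the adhesion molecule gene CEACAM6 at -0.87 ± 0.077 and the transcription factor gene SIM1 at -0.86 ± 0.091 (log2, SE, n = 5). The falls of KY, the plakophilin gene PKP2, ELFN2, the small GTPase gene RAB37 and the rhodopsin kinase gene GRK1 ranged from -0.76 to -0.69 on the log2 scale. KY had the largest edgeR adjusted p of the 10 falls, 0.00371.

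NF-kB feedback and target genes rose together at 5 µg/ml. Of 18 members tested, 15 rose and none fell, or 16 adjusted over the list alone, and the median log2 fold change was 0.90 (camera adjusted p = 2.58e-46). TNFAIP3, which encodes the ubiquitin-editing inhibitor of NF-kB signalling A20, rose from 22.3 ± 1.68 to 86 ± 8.11 CPM, RELB, an NF-kB subunit, from 12.2 ± 1.04 to 42.6 ± 4.23, and NFKBIA, the inhibitor IkB-alpha, from 42.9 ± 2.64 to 98 ± 3.44 (SD, n = 5).

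Among inflammatory cytokines and chemokines, 9 of 20 members rose and none fell, or 10 adjusted over the list alone, with a median log2 fold change of 0.48 (camera adjusted p = 1.82e-14, and 2.37e-05 with an estimated correlation). TNF rose by 1.24 ± 0.096, IL1B by 1.88 ± 0.19, CCL2, a monocyte chemokine gene, by 2.22 ± 0.43 and CCL5 by 0.45 ± 0.042 (log2, SE, n = 5). CCL2 was low, at 0.172 ± 0.124 CPM in control and 0.802 ± 0.117 CPM at 5 µg/ml (SD, n = 5). Interferon-stimulated genes had 10 of 25 members higher and none lower, or 16 higher and 1 lower adjusted over the list alone, with a median of 0.50 (camera adjusted p = 2.48e-14, and 0.00043 with an estimated correlation). OAS3, an antiviral oligoadenylate synthase gene, rose by 1.26 ± 0.057, IFI6 by 0.78 ± 0.063 and IFIH1, a cytosolic sensor of double-stranded RNA, by 0.66 ± 0.064 (log2, SE, n = 5).

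Pattern recognition and antigen presentation genes also moved up as groups. In the inflammasome and pattern recognition list 10 of 22 members rose and 2 fell, or 11 and 3 adjusted over the list alone (median log2 fold change 0.20, camera adjusted p = 7.99e-06). NOD2, a sensor of bacterial cell wall fragments, rose by 1.14 ± 0.082, P2RX7, an ATP-gated channel gene, by 0.90 ± 0.10 and TLR8, an endosomal RNA receptor gene, by 3.05 ± 0.36 from a low level of 0.2 ± 0.138 CPM (SD, n = 5). TLR4, the endotoxin receptor gene, fell by 0.34 on the log2 scale (SE 0.064), while TLR2 had a log2 fold change of 0.06 ± 0.045 (edgeR adjusted p = 0.512). Of 22 antigen presentation genes, 10 rose and none fell, or 13 adjusted over the list alone (median 0.25, camera adjusted p = 1.13e-12). CD74, the invariant chain of class II complexes, rose by 0.61 ± 0.033, TAPBP by 0.29 ± 0.027 and HLA-B by 0.36 ± 0.027 (log2, SE). Reads from HLA genes can be split between near-identical copies, so single HLA values are uncertain.

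Macrophage differentiation genes had 9 of 26 members higher and 1 lower, or 11 and 1 adjusted over the list alone, with a median log2 fold change of 0.16 (camera adjusted p = 1.19e-08). ITGAM, the alpha chain of the Mac-1 integrin, rose from 42 ± 1.02 to 64 ± 1.9 CPM (SD, n = 5). Integrins and CYR61 receptors had 7 of 21 members higher and 2 lower, or 7 and 4 adjusted over the list alone (median 0.082, camera adjusted p = 0.000207). ITGB2, the beta chain that pairs with ITGAM, rose by 0.43 ± 0.025 and the hyaluronan receptor gene CD44 by 0.50 ± 0.034 (log2, SE). In the list of matrix, matrix protease and plasminogen genes 9 of 23 members rose and 2 fell, or 12 and 4 adjusted over the list alone (median 0.18, camera adjusted p = 8.79e-07), led by MMP9, ADAMDEC1 and the proteoglycan gene VCAN at 0.47 ± 0.036.

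The fixed list of immature myeloid granule genes, which also holds S100A8, S100A9 and S100A12, split by member. Its name describes the list and not each member. At 5 µg/ml 4 of 16 rose and 10 fell, or 4 and 11 adjusted over the list alone. The median log2 fold change was -0.23 and camera placed the list lower (adjusted p = 5.72e-06), while the mean was 0.12. CTSG, PRTN3 (proteinase 3) and ELANE (neutrophil elastase) fell, with PRTN3 going from 4007 ± 73.1 to 2877 ± 78.3 CPM and ELANE from 1735 ± 56 to 1456 ± 44.6 CPM (SD, n = 5). S100A8 and S100A9, calcium-binding proteins that form calprotectin, rose, S100A9 from 86.7 ± 4.24 to 188 ± 6.12 CPM and S100A8 from 13.8 ± 0.589 to 31.6 ± 1.72 CPM (SD, n = 5). The other members that rose, S100A12, which encodes calgranulin C, and the lysozyme gene LYZ, are named after their values were seen, as are PRTN3 and ELANE at this dose.

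**Figure D2:**
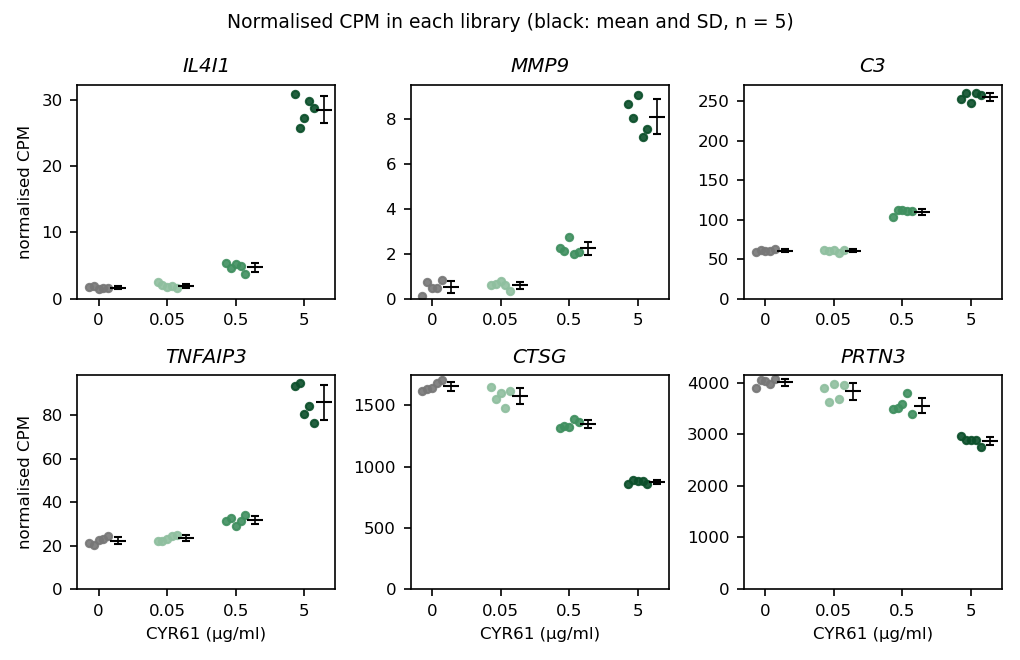
Normalised CPM (y axis, linear, separate scale per gene) of IL4I1, MMP9, C3, TNFAIP3, CTSG and PRTN3 in each library at 0, 0.05, 0.5 and 5 µg/ml CYR61 (x axis). Coloured points are single libraries, spread sideways only to show them, and black bars are the mean and SD of 5 libraries. C3 had means of 60.7, 60.6, 110 and 256 CPM from control to 5 µg/ml, and CTSG 1656, 1580, 1346 and 876 CPM.

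Angiogenic growth factor genes had 6 of 13 members higher and none lower, also 6 adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 2.84e-09). VEGFA rose from 24.5 ± 2.72 to 45.3 ± 2.22 CPM and TYMP, which encodes thymidine phosphorylase, from 42.1 ± 2.87 to 85.1 ± 6.99 CPM (SD, n = 5). Chemotactic and homing receptor genes had 6 of 15 members higher and 1 lower, or 10 and 2 adjusted over the list alone (median 0.24, camera adjusted p = 2.34e-05). C3AR1, the receptor of complement C3a, rose by 2.30 ± 0.29, CXCR4 by 0.24 ± 0.044 and CCR1 by 0.24 ± 0.048 (log2, SE, n = 5). Among antioxidant and NRF2 target genes 8 of 20 rose and none fell, or 10 adjusted over the list alone (median 0.17, camera adjusted p = 4.43e-08). The ferritin genes FTH1 and FTL rose by 1.09 ± 0.068 and 0.24 ± 0.024 (log2, SE), with the limit that both have many near-identical pseudogenes, and the autophagy adaptor gene SQSTM1 by 0.28 ± 0.04.

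S phase and mitosis genes rose by small amounts. Of 40 members, 14 rose and none fell, or 20 and 1 adjusted over the list alone, with a median log2 fold change of 0.092 (camera adjusted p = 1.19e-08). The proliferation marker MKI67 went from 437 ± 9.8 to 502 ± 8.2 CPM and CDC20, an activator of the anaphase-promoting complex, from 728 ± 17.1 to 814 ± 14.2 CPM (SD, n = 5). Of 57 replication-dependent histone genes, 27 rose and none fell, or 37 adjusted over the list alone (median 0.11, camera adjusted p = 1.82e-14). That list call was lost with adjusted p = 0.0944 with an estimated correlation. H2BC11 rose by 0.21 ± 0.034, H2BC17 by 0.20 ± 0.032 and H1-4 by 0.17 ± 0.031 (log2, SE), and near-identical histone copies leave the values of single members uncertain. The histone share of all counts was 0.981% in control and 1.06% at 5 µg/ml (exact permutation test, two-sided, n = 5, p = 0.00794, the smallest this design allows, and 0.0715 adjusted over 27 comparisons of composition).

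Cytosolic ribosomal protein genes had none of 83 members higher and 12 lower, or 14 lower adjusted over the list alone, with a median log2 fold change of -0.025 (camera adjusted p = 0.00107, but adjusted p = 0.425 with an estimated correlation). RPL10 fell by 0.11 on the log2 scale (SE 0.025), and RPL13A by 0.10 (SE 0.024), with the limit that ribosomal protein genes have many pseudogenes. Of 13 mitochondrially encoded genes, 4 fell and none rose, or 5 adjusted over the list alone (median -0.087, camera adjusted p = 0.000495, but adjusted p = 0.278 with an estimated correlation). MT-ND3, a subunit of respiratory complex I, had a log2 fold change of -0.14 (edgeR adjusted p = 0.00382). Among the 4 that fell, MT-ND5 lost its call without control replicate 2 (0.0532) and MT-ND4 without control replicate 2 or 3 or without 5 µg/ml replicate 3 or 4 (up to 0.0919). Ribosomal protein genes made up 5.04% of counts in control and 4.89% at 5 µg/ml, and mitochondrially encoded genes 3.79% and 3.59% (exact permutation test, adjusted p = 0.0715 and 0.0859).

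Other list changes at 5 µg/ml concerned stress and metabolic genes. Hypoxia and glycolysis genes had 7 of 23 members higher and none lower, or 10 adjusted over the list alone (median log2 fold change 0.10, camera adjusted p = 2.65e-06, but adjusted p = 0.082 with an estimated correlation), with HK2, a hexokinase gene, at 0.46 ± 0.054. Immediate-early and AP-1 genes had 5 of 25 higher and 1 lower, or 7 and 2 adjusted over the list alone (median 0.25, camera adjusted p = 0.000207, but adjusted p = 0.294 with an estimated correlation). Within it the transcription factor genes KLF4 and KLF6 rose by 0.60 ± 0.049 and 0.38 ± 0.055 (log2, SE). IER3 had a larger log2 fold change of 3.65 (edgeR adjusted p = 0.000265), but missed the expression or separation condition for the largest rises. Of 20 p53 target genes 3 rose and none fell, or 6 and 1 adjusted over the list alone (median 0.12, camera adjusted p = 0.000155). BTG2, an antiproliferative gene, rose by 0.96 ± 0.12, and TNFRSF10B, a death receptor gene, by 0.34 ± 0.059 (log2, SE). Heat shock genes had 5 of 13 members higher and 1 lower, the same counts adjusted over the list alone (median 0.061, camera adjusted p = 0.0253, but adjusted p = 0.188 with an estimated correlation). HSPH1 and HSP90AB1 rose by 0.13 ± 0.03 and 0.11 ± 0.024 and HSPB1 fell by 0.15 on the log2 scale (SE 0.033). The heat shock call was also lost without control replicate 1 (camera adjusted p = 0.0548) or without 5 µg/ml replicate 5 (0.0585).

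The other 10 lists were not called at 5 µg/ml. For the CCN family and YAP target genes, 3 of 16 members rose and 2 fell, also 3 and 2 adjusted over the list alone (camera adjusted p = 0.453), with a median of -0.00024, a mean of 0.011 and an upward test direction. The mRNA of CYR61 itself, CCN1 (ENSG00000142871), measured 4.81 ± 0.792 CPM in control, 5.11 ± 1.27 at 0.5 µg/ml and 4.73 ± 1.03 CPM at 5 µg/ml (SD, n = 5), a log2 fold change at 5 µg/ml of -0.02 ± 0.19 (SE, edgeR adjusted p = 0.98). CCN2, a related matricellular protein gene, had a log2 fold change of -0.36 ± 0.29 (adjusted p = 0.594). The receptor kinase gene AXL rose by 0.50 ± 0.06 and ARHGEF17 fell by 0.30 on the log2 scale (SE 0.046).

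The comparison of 0.5 µg/ml with control asked whether a 10 times lower dose changed expression. C3 (ENSG00000125730), the central complement component, rose from 60.7 ± 1.75 to 110 ± 3.68 CPM (SD, n = 5), a log2 fold change of 0.86 ± 0.033 (SE). MMP9 rose 4.34-fold to 2.24 ± 0.299 CPM and IL4I1 2.9-fold to 4.73 ± 0.656 CPM (SD, n = 5). CHST2 rose by 0.57 ± 0.11 and RELB by 0.52 ± 0.069 (log2, SE). CTSG fell to 1346 ± 31.9 and PRTN3 to 3555 ± 152 CPM (SD, n = 5), SEL1L3 fell by 0.17 (SE 0.032) and MLC1 by 0.16 (SE 0.027) on the log2 scale. These 9 genes kept their call in all 20 fits that left out 1 library.

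In that comparison 65 genes changed by edgeR's quasi-likelihood test, 49 higher and 16 lower, 50 of them by less than 1.5-fold, and 37 changed without control replicate 5. Replicates 4 and 5 at 0.5 µg/ml differed most of the 40 pairs within groups, with a chi-square per gene of 9.43. Another grouping of the control and 0.5 µg/ml libraries gave 213 genes. DESeq2 called 99 genes, edgeR with no filter beyond 1 read 99, and edgeR with 1 surrogate variable 137. The groups did not overlap for 55 of the 65 genes, and were separated in 1.37% of all genes tested, where chance gives 0.794%. The other genes with the largest changes under the fixed rule were ADAM28, SULF2, CALN1, CXCL8 and TP63, which rose by 0.56 to 0.96, and UGT3A2, SLC25A10, WNT7B, AIG1, FAM189B and ELANE, with log2 fold changes of -0.36 to -0.13. UGT3A2 lost its call without control replicate 4 (edgeR adjusted p = 0.102). Each of the other 10 lost its call in 3 to 8 of the 20 fits that left out 1 library (adjusted p up to 0.309), and every control and every 0.5 µg/ml library was the one left out in at least 1 of those fits, as was 0.05 µg/ml replicate 5 for FAM189B.

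Of the 30 lists, 11 were called at 0.5 µg/ml by camera and 6 with an estimated correlation. NF-kB feedback and target genes had 6 of 18 members higher and none lower, or 11 adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 9.26e-14, and 0.0011 with an estimated correlation), with TNFAIP3 at 0.51 ± 0.058 and ICAM1 at 0.95 ± 0.18 (log2, SE). Inflammatory cytokines had 1 of 20 higher, CXCL8, also 1 adjusted over the list alone (median 0.11, camera adjusted p = 0.00221), and angiogenic growth factors 1 of 13, also CXCL8 and also 1 adjusted over the list alone (median 0.14, camera adjusted p = 0.00485). CXCL8 lost its own call in 6 of the 20 fits that left out 1 library (edgeR adjusted p up to 0.102). Macrophage differentiation genes had 1 of 26 higher, MMP9, also 1 adjusted over the list alone (median 0.078, camera adjusted p = 0.00307). No member of the inflammasome and pattern recognition list of 22 genes was called over all genes, against 6 higher adjusted over the list alone (median 0.077, camera adjusted p = 0.022), and the list lost its call without control replicate 1 (0.0661), control replicate 2 (0.0627), 0.5 µg/ml replicate 2 (0.0677) or 0.5 µg/ml replicate 3 (0.056). Structural and nuclear noncoding RNAs had 1 of 8 members higher, the spliceosomal RNA gene RNU4-1 at 0.61 ± 0.11 (log2, SE), or 2 adjusted over the list alone (median 0.088, camera adjusted p = 0.00286), and RNU4-1 and RNU4-2 are near-identical copies.

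The other 5 lists called at 0.5 µg/ml lost their call with an estimated correlation. Interferon-stimulated genes had 1 of 25 members higher, OAS3 at 0.43 ± 0.058, also 1 adjusted over the list alone (camera adjusted p = 0.000356, but adjusted p = 0.0527 with an estimated correlation). Immature myeloid granule genes had 2 of 16 higher and 3 lower, or 3 and 10 adjusted over the list alone, with a median of -0.096, a mean of 0.0096 and a downward test direction (camera adjusted p = 0.000356, but adjusted p = 0.0507 with an estimated correlation), and S100A9 rose from 86.7 ± 4.24 to 107 ± 3.8 CPM (SD, n = 5). Ribosomal protein genes had 1 of 83 lower and none higher, or 2 lower adjusted over the list alone (camera adjusted p = 6.99e-05, but adjusted p = 0.416 with an estimated correlation). That list also lost its call without 0.5 µg/ml replicate 1 (camera adjusted p = 0.113). Matrix genes had 3 of 23 higher and none lower, or 5 adjusted over the list alone (camera adjusted p = 0.0352, but adjusted p = 0.184 with an estimated correlation). That call was also lost without control replicate 1 (0.0661) or 2 (0.138), or without 0.5 µg/ml replicate 2 (0.0572), 3 (0.0568) or 4 (0.18). Of its 3 members called, VCAN lost its call without control replicate 2 (edgeR adjusted p = 0.0607) and ADAMDEC1 without control replicate 2, 3 or 4 or without 0.5 µg/ml replicate 2 or 4 (up to 0.069). Antigen presentation genes had 1 of 22 higher, CD74 (a call lost in 5 of the 20 fits that left out 1 library, edgeR adjusted p up to 0.186), or 3 adjusted over the list alone (camera adjusted p = 0.0397, but adjusted p = 0.287 with an estimated correlation). That call was also lost without control replicate 1 (0.243) or 2 (0.0627), or without 0.5 µg/ml replicate 2 (0.0904), 3 (0.102) or 4 (0.152).

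**Figure D3:**
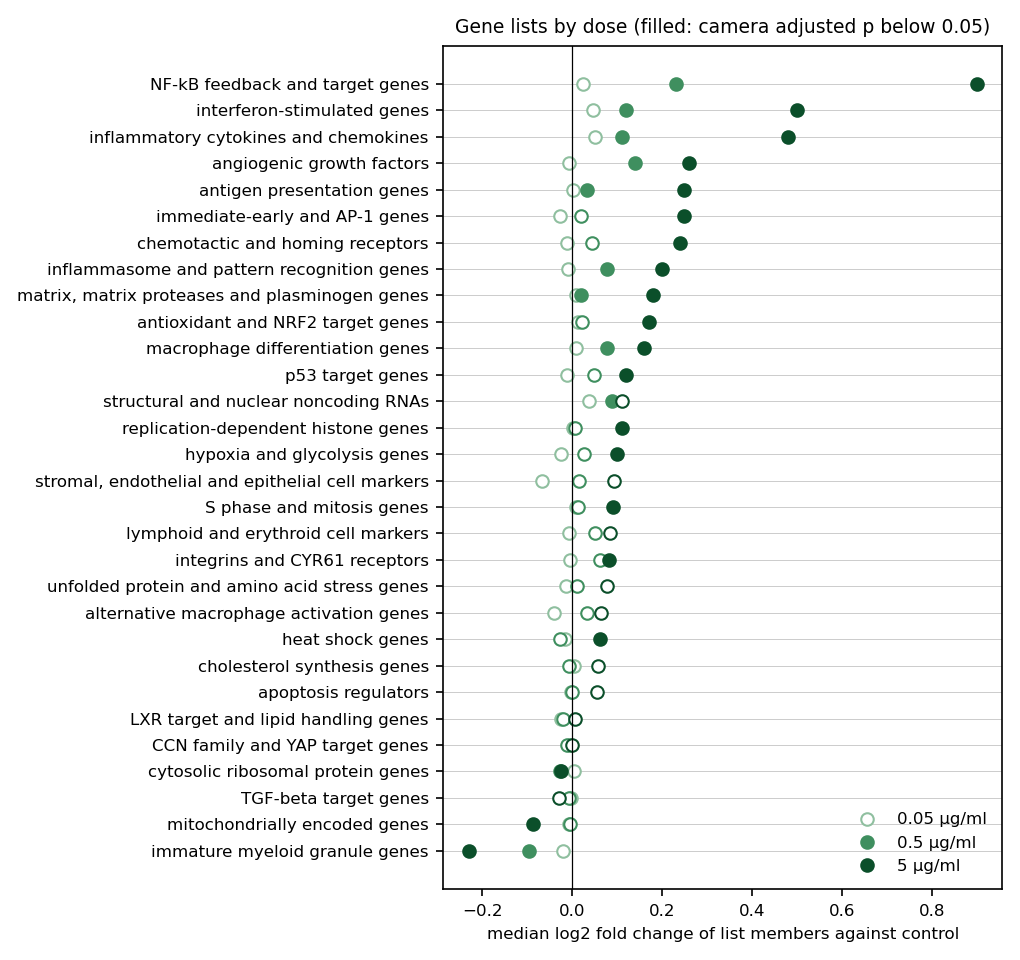
Median log2 fold change against control (x axis) of the tested members of each of 30 gene lists (y axis) at 0.05, 0.5 and 5 µg/ml CYR61 (light, middle and dark green, n = 5 libraries per group), with filled points for lists called by camera and open points for the others. The NF-kB list had medians of 0.025, 0.23 and 0.90 and the granule gene list -0.096 and -0.23 at 0.5 and 5 µg/ml.

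The comparison of 0.05 µg/ml with control asked the same of the lowest dose. C3 measured 60.6 ± 1.49 CPM against 60.7 ± 1.75 in control, MMP9 had a log2 fold change of 0.21 ± 0.27 (SE), CXCL8 of 0.21 ± 0.15, TNF of -0.15 ± 0.1, CCN1 of -0.04 ± 0.19 and ITGAM of 0.03 ± 0.044 (n = 5). No gene that passed the filter was called by edgeR, and DESeq2 and limma voom on those genes also called 0. Without that filter edgeR called some genes, counted in the part on processing. An unadjusted p below the threshold was reached by 988 genes in edgeR (4.01% of those tested), 1083 in DESeq2 and 1185 in voom. None of the 30 lists was called by camera or with an estimated correlation. The smallest camera adjusted p was 0.286, for inflammatory cytokines and chemokines with a median of 0.051. Without control replicate 1 camera called histone genes (0.0238) and LXR target genes (0.0322), without control replicate 3 inflammatory cytokines (0.0296), and without 0.05 µg/ml replicate 5 immediate-early genes (4.04e-05).

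Direct comparisons of adjacent doses asked at which step expression moved. From 0.05 to 0.5 µg/ml 35 genes changed, 32 higher and 3 lower, with C3 again at 0.86 ± 0.033 (log2, SE, edgeR adjusted p = 2.9e-29) and S100A9 at 0.30 ± 0.036 (5.49e-08). Another grouping of those libraries gave 446 genes, and the count of 35 also moved with the filter and a surrogate variable, as given below. From 0.5 to 5 µg/ml 1238 genes changed, 829 higher and 409 lower, 1006 of them by less than 1.5-fold. C3 rose by a further 1.22 ± 0.032, TNF by 1.22 ± 0.096 and S100A9 by 0.81 ± 0.035 (log2, SE, edgeR adjusted p between 1.98e-38 and 3.21e-15). TNF had a log2 fold change of 0.02 ± 0.1 at 0.5 µg/ml against control (edgeR adjusted p = 0.991).

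A slope over equal steps of dose level, from 0 in control to 3 at 5 µg/ml, was called by edgeR for 1832 genes, 1080 rising and 752 falling. The steepest rises under the fixed rule were those of IGFBP3 at 1.70 ± 0.15, IL4I1 at 1.57 ± 0.12, MMP9 at 1.51 ± 0.1, ICAM1 at 1.23 ± 0.12 and EBI3 at 1.06 ± 0.11 per level (log2, SE, n = 20). MSRB3 fell most steeply under that rule, with a slope of -0.32 ± 0.037, followed by UGT3A2 and CTSG at -0.30, CEACAM6 at -0.29 and SIM1 at -0.26 per level. The 15 libraries below 5 µg/ml, an alternative chosen after seeing the data that also has fewer libraries and dose levels, gave 54 genes.

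Of the genes called at 0.5 µg/ml, 48 of the 49 higher and 15 of the 16 lower were also called in that direction at 5 µg/ml, where independent lists of these sizes would share 2.23 and 0.51. Both comparisons use the same 5 controls, so the 2 sets of calls are not independent. With the controls split into 2 and 3 libraries, so that each comparison had its own, a median of 30 genes over 10 splits were called in both (range 26 to 38), and a median of 32 were called at 0.5 µg/ml (range 27 to 46). The change was larger at 5 µg/ml for 62 of the 63 shared genes, and 57 of them also passed the direct comparison of 5 with 0.5 µg/ml. The genes called at 0.5 µg/ml only were RNU4-1, with log2 fold changes of 0.61 and 0.30 at the 2 doses, and AC091978.1, a lncRNA gene named after its values were seen, with -1.53 and -0.19. In the direct comparison of 5 with 0.5 µg/ml, RNU4-1 had a log2 fold change of -0.31 ± 0.10 (SE, edgeR adjusted p = 0.0615) and AC091978.1 rose by 1.34 ± 0.37 (SE, 0.0154).

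**Figure D4:**
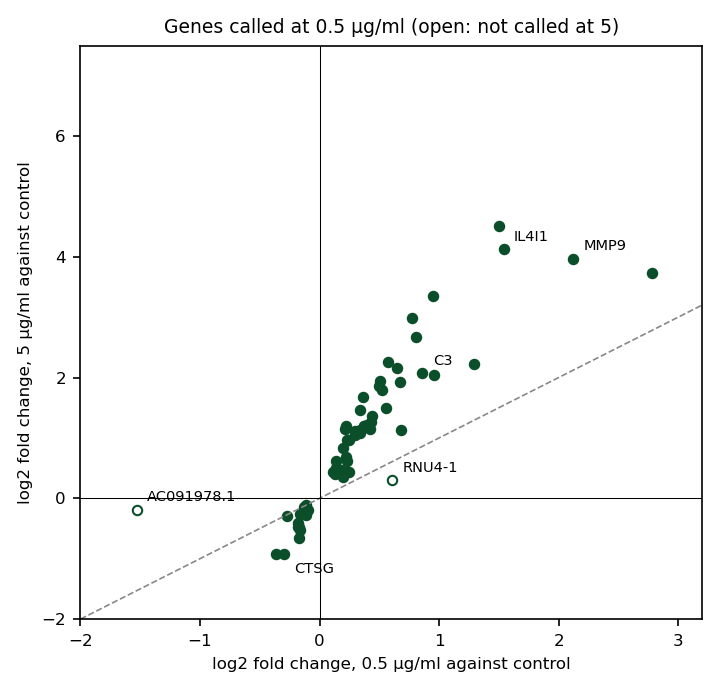
Log2 fold change against control at 0.5 µg/ml (x axis) and at 5 µg/ml (y axis) of the 65 genes called at 0.5 µg/ml, each point a gene and n = 5 libraries per group. Filled points were also called at 5 µg/ml, open points were not, and the dashed line marks equal changes. IL4I1 lies at 1.54 and 4.13, above the line, and RNU4-1 at 0.61 and 0.30, below it.

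When genes called at 5 µg/ml were chosen with one part of the controls and measured against the other part, their log2 fold changes in the direction of choice had medians over 10 splits of 0.287 at 5 µg/ml, 0.0629 at 0.5 µg/ml and 0.00698 at 0.05 µg/ml. Only the controls were split, and the same 5 µg/ml libraries served for choosing and for measuring. The value at 5 µg/ml therefore keeps a bias from the choice on the treated side, which the 2 lower doses do not share. The same direction was seen at 0.5 µg/ml in 82.3% of the chosen genes (range 71.5% to 88.0%) and at 0.05 µg/ml in 55.8% (range 45.2% to 61.3%).

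The authors' deposited tables of their own comparisons list 0, 62 and 2299 genes past an adjusted p of 0.05 at 0.05, 0.5 and 5 µg/ml, among 17964 genes. At 0.5 µg/ml 50 genes and at 5 µg/ml 1834 genes were called in the same direction by the authors' deposited table and by edgeR, and none in opposite directions. For C3 the authors' deposited table gives log2 fold changes of 0.86 at 0.5 µg/ml and 2.07 at 5 µg/ml, the values that edgeR gave. For IGFBP3 at 0.5 µg/ml the authors' deposited table gives 1.43 with an adjusted p of 0.0539, while edgeR called it with an adjusted p of 0.0101.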

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

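The predictions for all tests in this part were written before their results were seen, but the use of matched genes against scaling was chosen after. In 212 groups of 5 libraries, over 53 measures that included 44 genes, 1 library stood apart from the other 4 in 10 groups (4.72%), where chance gives about 1 in 20.

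C3, the complement component gene, measured 103 CPM in 0.5 µg/ml replicate 1, against 111 to 112 CPM in the other 4 libraries of its group. SIM1 in the same library measured 13.4 CPM against 9.91 to 10.9. SULF2, an extracellular sulfatase gene, measured 5.48 CPM in 0.5 µg/ml replicate 4 (others 3.27 to 3.9) and 7.45 CPM in 5 µg/ml replicate 5 (others 4.79 to 5.29). UGT3A2 measured 17.6 CPM in control replicate 4, against 14.8 to 15.6. Histone genes held 0.943% of counts in control replicate 1 (others 0.985% to 0.998%) and 1.01% in 5 µg/ml replicate 5 (others 1.06% to 1.08%). In control replicate 1 misc_RNA genes held 2.55% (others 2.72% to 2.77%), in 5 µg/ml replicate 5 lncRNA genes held 2.32% (others 2.2% to 2.23%), and in 0.5 µg/ml replicate 4 snoRNA genes held 0.121% (others 0.146% to 0.152%). By library, 5 µg/ml replicate 5 had 3 of the 10 values, control replicate 1, 0.5 µg/ml replicate 1 and 0.5 µg/ml replicate 4 had 2 each, and control replicate 4 had 1.

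The rise of NF-kB feedback and target genes such as TNFAIP3 and RELB at 5 µg/ml was tested against a difference in depth between groups. After every library was thinned to the smallest total, 15 of the 15 called members were still called higher, which argues against depth. The other explanation weighed was endotoxin carried in with the added protein, since endotoxin also activates NF-kB. It stays open, because 0 libraries held the protein after endotoxin removal or neutralisation. An effect of CYR61 and an effect of such a contaminant cannot be told apart here.

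The rise of replication-dependent histone genes such as H2BC11 at 5 µg/ml, a list call lost with adjusted p = 0.0944 with an estimated correlation, was tested against gene length and GC content bias. After removal of the length and GC trends, which moved 1721 genes by more than 0.05 on the log2 scale, the list median was 0.13 against 0.11 before and the mean level per library differed by 0.13 (95% exact permutation interval 0.082 to 0.17, n = 5), which argues against this bias as the whole cause. A larger capture of RNAs without a poly(A) tail stays open, since the mean log2 level of 46 abundant snRNA, snoRNA and misc_RNA genes moved by 0.0053 with an interval of -0.075 to 0.087 (exact permutation test, p = 0.825, n = 5). That interval lies below the histone estimate of 0.11, but it includes the 0.05 set as the limit in advance and overlaps the histone interval before correction (0.056 to 0.16), so a partial contribution is not excluded. The libraries were random-primed after ribosomal depletion, and no biological explanation of the histone pattern was tested.

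Among the lncRNA genes called at 5 µg/ml, 85 of 121 were lower (70.2%), against 38.6% of called protein-coding genes. Protein-coding genes matched on average expression had a median of 31.4% lower over 10000 draws (24% to 39.7%), which argues against the lower expression of lncRNA genes. With RLE factors or library totals, which moved values little, the smaller share was 68%. A shift in the scaling of the libraries acts on all genes alike, so the lower share among matched protein-coding genes argues against it. After removal of length and GC trends the share of called lncRNA genes lower was 67.1% (98 of 146, interval 59.1% to 74.2%), against 33.5% of protein-coding genes, which counts against length and GC bias as the whole cause. That interval treats the 146 genes as independent, so it does not measure the spread between libraries. No biological explanation was tested.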

How the results depend on the processing

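The slope over the libraries below 5 µg/ml is the only test in this part chosen after the result was seen. No result changed direction under any alternative where at least 1 of the fits passed the threshold. At 0.5 µg/ml against control the 65 genes became 99 with no filter beyond at least 1 read in any library, 99 with the DESeq2 Wald test, 137 with 1 surrogate variable, 31 at an FDR threshold of 0.01 and 5 with glmTreat against a fold change of 1.2. For the 1908 genes at 5 µg/ml the last 2 gave 1229 and 316. At 0.05 µg/ml, with 0 genes, no filter gave 7, 3 higher and 4 lower.

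Between 0.05 and 0.5 µg/ml the 35 genes became 56 with no filter, 3 with glmTreat and 58 with 1 surrogate variable. Between 0.5 and 5 µg/ml the 1238 genes became 173 with glmTreat, 756 at an FDR threshold of 0.01 and 1872 with 1 surrogate variable. The slope, with 1832 genes, gave 51, 1127 at 0.01, and 54 over the 15 libraries below 5 µg/ml. Stricter thresholds call fewer genes by construction. For the filter, DESeq2, the surrogate variable and the slope over 15 libraries the cause was not tested.

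Leaving out 1 library gave 37 (without control replicate 5) to 74 genes at 0.5 µg/ml and 1603 to 2049 at 5 µg/ml. Called lists ranged from 0 to 2 at 0.05 µg/ml, where 2 were called without control replicate 1 and 1 each without control replicate 3 and without 0.05 µg/ml replicate 5. They ranged from 8 to 13 at 0.5 µg/ml, where lists of hypoxia (without control replicate 3, 0.0467, control replicate 4, 0.0366, or 0.5 µg/ml replicate 1, 0.0304), chemotactic receptor (control replicate 4, 0.043, or 0.5 µg/ml replicate 1, 0.022), heat shock (control replicate 2, 0.0437, or 0.5 µg/ml replicate 5, 0.0277) and p53 target genes (control replicate 5, 0.0446) gained a call, and from 19 to 21 at 5 µg/ml. With an estimated inter-gene correlation 6 lists were called at 0.5 µg/ml and 14 at 5 µg/ml. With fry 11 and 23 lists were called. Fry lost antigen presentation genes at 0.5 µg/ml (0.0924) and ribosomal protein genes at both doses (0.227 and 0.0839). At 5 µg/ml it added the lists of unfolded protein stress (0.0255), apoptosis (0.00218), alternative activation (0.00437) and CCN family genes (0.0302), and at 0.5 µg/ml those of integrins (0.0288) and p53 targets (0.0206). Splitting the controls into 2 and 3 libraries lowered the genes shared by both doses from 63 to a median of 30 over 10 splits, in which the genes called at 0.5 µg/ml also fell, to a median of 32.

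Libraries of the same number were not closer across groups (mean correlation -0.043 over 30 pairs, range -0.40 to 0.50), so the numbers do not pair the libraries. With the replicate number as a block 57 genes were called at 0.5 µg/ml and 1771 at 5 µg/ml. With that block 10 lists were called at 0.5 µg/ml, where antigen presentation genes lost their call (camera adjusted p = 0.0524), and 20 at 5 µg/ml. CD74 (edgeR adjusted p = 0.0648) and FAM189B (0.0571) lost their call at 0.5 µg/ml with the block.

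Thinning every library to the smallest total gave 1843 genes at 5 µg/ml, against 1908. On simulated data at the real depth 18% of genes changed 1.1-fold and 94% of genes changed 1.5-fold were recovered at 5 µg/ml.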

Other observations

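None of the tests in this part was chosen after the result was seen. Stress and lipid genes moved in both directions at 5 µg/ml in lists that camera did not call. Unfolded protein and amino acid stress genes had 6 of 22 members higher and 2 lower, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0721), with CHAC1 at 0.57 ± 0.12 and VLDLR at -0.25 ± 0.036 (log2, SE, n = 5). Camera called that list without control replicate 4 (0.0244), control replicate 5 (0.0407) or 5 µg/ml replicate 2 (0.0341). Cholesterol synthesis genes had 1 of 23 higher, ACAT2, and 1 lower, TM7SF2, or 2 and 1 adjusted over the list alone (0.105), and those gene calls were lost in 5 and 4 of the 20 fits that left out 1 library (edgeR adjusted p up to 0.12 and 0.122). Camera called the cholesterol list without 5 µg/ml replicate 1 (0.0369). LXR target and lipid handling genes had 2 of 17 higher and 3 lower, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.409), with the fatty acid transporter CD36 at 0.65 ± 0.08. Apoptosis regulators had 4 of 22 higher and 1 lower, the same adjusted over the list alone (0.122), with BIRC3 at 2.17 ± 0.24 and BCL2 at -0.25 ± 0.03.

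Alternative macrophage activation genes had 2 of 12 higher, CD209 and TGFB1, and 1 lower, F13A1, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.143). TGF-beta target genes had 5 of 19 higher and 1 lower, or 5 and 4 adjusted over the list alone (0.565), with a median of -0.029, a mean of -0.0011 and an upward test direction, and SMAD7 rose by 0.26 ± 0.045 (log2, SE). Structural and nuclear noncoding RNAs had none of 8 members called, or 2 higher and 1 lower adjusted over the list alone (0.545). Lymphoid and erythroid cell markers had 1 of 5 higher, NKG7, also 1 adjusted over the list alone (0.305). Stromal, endothelial and epithelial cell markers had 1 of 7 higher, PECAM1, also 1 adjusted over the list alone (0.41), with a median of 0.093, a mean of -0.04 and an upward test direction. PECAM1 lost its call without control replicate 2 or without 5 µg/ml replicate 2 (edgeR adjusted p up to 0.0663).

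Each comparison was repeated on 100 splits of its libraries, the real split included. For the genes changed at 5 µg/ml, 1 split gave as many as the real 1908 and the highest other gave 52. The same count was found for 5 against 0.5 µg/ml (1 split, real 1238, highest other 300) and for the slope (1 split, real 1832, highest other 31). These counts lay under the limit set in advance, which argues against a chance assignment of single libraries to groups. They cannot exclude a chance difference between cultures, since the labels do not say whether the libraries of a group came from separate ones. The counts also stayed under that limit at 0.5 µg/ml for genes (2 splits, real 65, highest other 213) and lists (2 splits, real 11, highest other 12), and for 0.5 against 0.05 µg/ml (3 splits, real 35, highest other 446). The splits with 213 and 446 genes point to a structure among the libraries other than their dose. For these 3 results a chance alignment of such a structure with dose is therefore not excluded. For the 20 lists called at 5 µg/ml, 6 splits gave as many and the highest other 21, so chance was not excluded by this count, and the 5 others all kept 4 of the 5 libraries of each group together. At 0.05 µg/ml all 100 splits gave at least the real 0 genes (highest other 1) and all 100 the real 0 lists (highest other 8), as any split must when the real count is 0, so that rank says nothing about chance. Of the 99 other splits there, 74 gave at least 1 list by camera (median 2), although the real split gave 0 genes. At 0.5 and 5 µg/ml 82 and 91 other splits gave at least 1 list (medians 2 and 5), where a split can carry part of the dose effect. A camera call with the preset correlation can thus arise in a grouping that does not follow dose.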
